A study of Danio rerio with 12 samples.

How the data were processed

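Gene expression was measured in the gills of adult zebrafish (Danio rerio) kept in clean water or exposed for 96 h to metal oxide nanoparticles. Per the labels, CuO was given at 0.2 mg/L, ZnO at 4.8 mg/L and NiO at 17.5 mg/L, with 3 samples per group including the untreated controls, and each sample was a pool of gills from 10 fish. Per the labels' protocols, total RNA was taken up in Trizol, treated with DNase I, labelled with cyanine 3 (Low Input QuickAmp kit) and hybridised to an Agilent zebrafish array. The labels also speak of a dye swap, but each deposited file holds 1 channel, so the arrays were treated as one-colour.

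Each array came as a scanner file of 45220 spots, 43803 of them not controls. Per the file headers, the image was read with Feature Extraction 11.5.1.1, which wrote a background-subtracted processed intensity and flags for outliers, saturation and signal well above background. The array's own annotation was made on the danRer7 (Zv9) build, per the file headers, and no coordinates are given here. The submitters' processing notes name MAS5, whose version and role are not given in the sources used here. The deposited series table holds an intensity per probe on a linear scale. Setting each of its 12 columns against each scanner file showed the processed signals averaged per probe, equal within 0.1% for at least 99.9% of probes, with no centring or scaling between arrays. Column medians ran from 146 to 584. By the scanner files' links, only the columns for control 1 and NiO 3 held the array of the sample they name, and the other 10 columns held that of another sample. The scanner files, which carry each sample's own link, were therefore the main source, and the table as labelled was an alternative.

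Control spots and outlier spots (0.0594 to 1.80% of non-control spots per array) were left out, and repeated spots of a probe were averaged. The value analysed was log2 of the processed signal minus the 75th percentile of its array. A probe was tested if it was well above background on all 3 arrays of at least 1 group, and a gene was tested if it had at least 2 values in every group. Of 43603 probes, 26094 carried a RefSeq accession that matched 1 current gene symbol in a table of the GRCz12tu annotation, 0 matched several and 17509 stayed unnamed, among them 8262 with an Ensembl transcript name and RefSeq accessions without a match (27655 RefSeq probes in all). The named probes covered 13443 genes. Of 37406 probes tested, 23742 were named. Each gene was represented by its probe with the highest mean signal, which gave 12558 genes, 7071 of them with more than 1 tested probe. Different probes of a gene were called in opposite directions for 19 of 3350 genes with a called probe under CuO, 24 of 3260 under ZnO and 23 of 2839 under NiO.

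Groups were compared with limma 3.58.1 in R 4.3.3: a single fit of 4 group means, moderated variances and Benjamini-Hochberg adjustment within each contrast at an adjusted p of 0.05. The contrasts were each exposure against control, the 3 pairs of exposures, the mean of the 3 exposures against control and an F test over the 4 groups. Samples are separate pools of fish, so p-values measure the spread between pools. A gene that was not well above background on any array of 1 group is given as at least N-fold, from the bright group's mean against the higher of the dim probe's own signal and the lowest signal well above background on each array. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and with an estimated one, and the members called were also counted with p-values adjusted over the list alone.

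The lists, the tests, the rule for named genes and most of the alternatives below were chosen before the data were examined. There were 29 lists with 1504 members, of which 1462 had a current symbol and 1212 lay on the array: metallothionein and zinc transport, copper handling, iron handling, antioxidant and glutathione, heat shock proteins, endoplasmic reticulum stress, proteasome, ion transport and ionocytes, acute inflammation, complement, interferon response, lymphocyte, myeloid, erythrocyte, skeletal muscle, cardiac muscle, cartilage and bone, liver and plasma, epithelial and mucous cell markers, collagen and extracellular matrix, cell cycle, p53 pathway, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, aryl hydrocarbon receptor, circadian clock, immediate early genes and ribosomal proteins. A further 6 marker lists were added after the data were seen, for oocytes, testis, ovarian follicle, eye, pituitary and brain, and pancreas and intestine. The genes named against control were the 10 largest changes each way among called genes with all 3 exposed arrays on the same side of all 3 controls and signal well above background on at least 2 arrays of both groups, passing over symbols that only number a clone or locus, up to 5 each way known only as a bound, up to 4 called members of each list, and a fixed set of stress and metal genes given whatever their result (hif1ab belonged to it and was not measured). Between exposures the 5 smallest p-values were named, since no gene passed. Of the genes chosen by this rule, those that say most about each list are printed.

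The alternatives chosen in advance were quantile normalization, a 75th percentile over probes well above background on all 12 arrays, no filter on background, a filter on all 12 arrays, the mean of all probes of a gene, all probes named or not, array weights, moderated variances with trend and robust settings, only the groups compared, the replicate number, the slide or the scan as a block, an adjusted p of 0.01, a log2 difference of at least 1, an estimated correlation in the list test, the deposited table as labelled and each array left out in turn. Added after the data were seen were normexp (offset 50) on the median signal, centring on ribosomal protein genes, the mean of the oocyte markers as a covariate and 3 sets of arrays left out. Slide and scan coincided with the replicate number, each of the 3 slides holding 1 array of every group, and the position on the slide coincided with the group.

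The fit was tested on simulated data with 200 of 12558 genes changed between CuO and control. It recovered 1 of 67 genes at a log2 difference of 1, 27 of 67 at 2 and 51 of 66 at 4, with 8 false calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and statmod 1.5.0 was loaded beside limma. A block entered the fit as added terms of the model, and no correlation within blocks was estimated.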

Results

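Gill RNA of 12 pools of adult zebrafish was hybridised to one-colour Agilent arrays. There were 3 control pools and 3 pools each after 96 h in water with CuO (0.2 mg/L), ZnO (4.8 mg/L) or NiO (17.5 mg/L) nanoparticles, metal oxide particles that can release metal ions. Per the labels, each dose was set from that particle's median lethal concentration. Between 75.5% and 88.4% of the spots lay well above background on each array, 0 spots were saturated, and the 75th percentile of the processed signal ran from 1383 to 3314. Across genes, arrays of a group correlated at r = 0.912 to 0.924 in the controls, 0.857 to 0.966 under CuO, 0.823 to 0.938 under ZnO and 0.818 to 0.925 under NiO. The median SD within a group was 0.60 on the log2 scale, and the 3 arrays per group limit the precision.

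Levels are log2 signals relative to the 75th percentile of the array, as mean ± SD of n = 3 pools, and differences are log2 with their standard error (SE). The median gene lay 0.41 above the controls under CuO, 0.32 under ZnO and 0.27 under NiO, so list medians are given relative to that gene. Adjusted p-values are limma's. Each gene named as risen or fallen had its 3 exposed arrays on the same side of all 3 controls unless stated. The 10 largest rises or falls are further limited to genes well above background on at least 2 arrays of both groups, passing over symbols that only number a clone or locus. In the deposited series table, most columns (10 of 12) hold the array that the scanner files link to another sample. Read by its column names, limma called 0 genes of that table for CuO, ZnO or NiO against the controls (254, 229 and 554 at an unadjusted p under 0.05), and all other values are from the scanner files.

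Transcripts of other tissues differed between these gill arrays. The median level of 52 oocyte and early germ cell genes, a list added after the data were seen, was 2.76, 2.80 and 3.05 on the controls and 1.58 on NiO 1. On the other 8 arrays it lay between -4.81 and -3.28. The median of 32 eye lens and retina genes was -5.88 on control 3, -6.28 on CuO 3, -6.70 on ZnO 1 and -6.55 on NiO 2, but 0.08 to 1.87 on the others. The median of 24 pituitary and brain genes was lowest on the same 4 arrays (-4.28, -4.41, -4.35 and -4.87). Member by member, 5 of these 24 lay lower on all 4 arrays than on every other array, against 31 of the 32 eye genes. On ZnO 1 the medians of 26 pancreas and intestine genes (-4.22) and 42 liver and plasma protein genes (-3.05) were low as well.

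**Figure D1:**
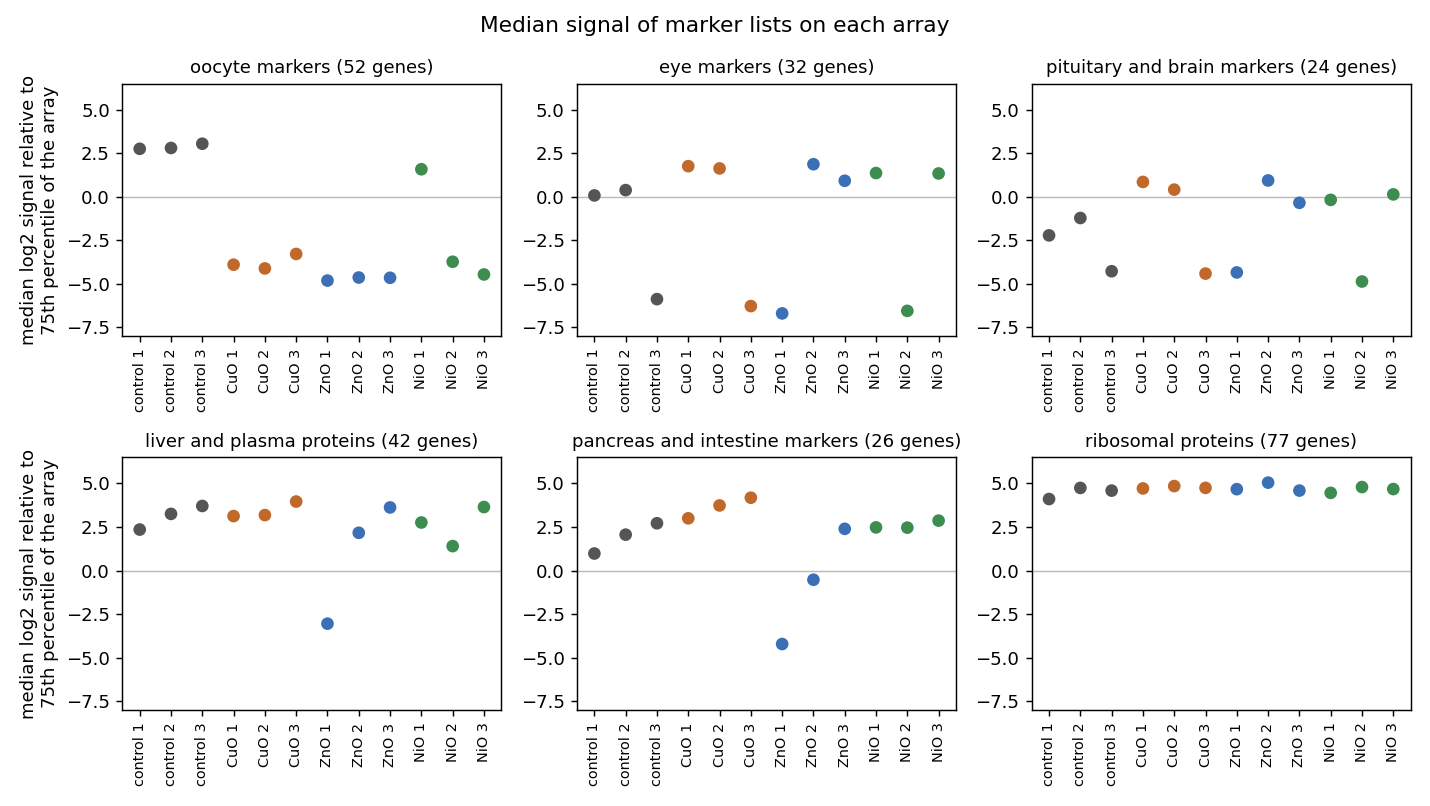
Median log2 signal relative to the 75th percentile of the array (vertical axis) of 6 gene lists on each of the 12 arrays (horizontal axis, by group), 1 point per array. Oocyte medians are high on the 3 controls and NiO 1, and eye and pituitary medians are low on 1 array of every group.

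CuO was compared with the controls to find the gill genes that respond to copper oxide particles. Egg coat genes were among the largest falls, and most yolk genes fell too. The egg envelope glycoprotein gene zp3e was -6.49 ± 0.71 under CuO and 4.15 ± 0.08 in the controls (difference -10.64, SE 1.73, adjusted p = 0.0031). The yolk precursor vtg4 was -4.51 ± 0.54 and 2.65 ± 1.5 (-7.17, SE 0.96, adjusted p = 0.00165, or -7.97 without control 2 and -6.48 without control 3). Members of the cell cycle list fell with them, such as the mitotic kinase aurka (-2.70 ± 0.49 and 2.48 ± 0.18). The inducible chaperones hsp90aa1.2 and hsp70l rose 5.06-fold (adjusted p = 0.00318) and 2.95-fold (adjusted p = 0.00458), and the keratin krt1-c5 rose 4.57-fold (adjusted p = 0.00231). In all, 1433 genes rose and 1714 fell of 12558 tested (5049 at an unadjusted p under 0.05), or 607 and 1931 with arrays centred on ribosomal protein genes. At least 8-fold changes were called for 539 genes downward and 40 upward.

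Egg coat genes also fell under CuO in zp3f.1 (-10.61, SE 1.86, or -11.24 without CuO 3), zpcx (-9.83, SE 1.96) and zp3a.1 (-9.31, SE 1.99). The same 10 largest falls held btg4, which licenses the clearance of maternal mRNA (-9.97, SE 1.95), gtf3ab, a TFIIIA of 5S RNA transcription (-9.48, SE 2.04, or -10.36 without CuO 3), the claudin cldnd (-9.60, SE 1.92), the cyclin ccnp (-9.30, SE 1.67) and retsatl (-9.91, SE 1.99). The call of the egg coat gene zp2.5 (-9.76, adjusted p = 0.0187) was lost without control 3 (-9.71) or CuO 2 (-9.46), each at an adjusted p of 0.056. Not well above background on any CuO array were zp2l1, at least 1222-fold lower, and lectin, at least 786-fold lower. Of the 52 oocyte genes, 42 fell and 0 rose, or 44 and 1 adjusted over the list alone. Of 102 cell cycle genes, 69 fell and 0 rose, or 73 and 4 adjusted over the list alone. Among them was ccnb1, the cyclin of mitotic entry (-5.18, SE 0.95). The cell cycle median was -2.92 (adjusted p = 4.19e-23, or adjusted p = 0.583 with an estimated correlation), on the same arrays where oocyte genes were low. Of 42 liver and plasma genes, 4 fell and 1 rose, with the same counts adjusted over the list alone. The fallen were vitellogenins, vtg7 the furthest (-7.68, SE 1.11). The vitellogenin vtg5 overlapped the controls (0.943 to 1.69 under CuO, 0.664 to 3.79 in the controls).

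The 10 largest rises under CuO held illr1, an immune-related lectin-like receptor (-1.60 ± 0.39 and -6.99 ± 2.51, difference 5.39, SE 1.02, or 6.69 without control 1 and 4.19 without control 2). Of the 10, these also kept their calls with each array left out: the transglutaminase-like tgm1l4 (4.59, or 5.55 without control 2 and 3.75 without control 3), cyp8b1.3 of the bile acid hydroxylase family (3.92, or 4.65 without CuO 1), the matrix glycoprotein tinagl1 (3.45, SE 0.71) and the opioid peptide precursor pdyn (3.35, or 4.10 without control 2). The other 5, cfap299, pimr166, ccdc83, npb and actn2b, were called at 3.46 to 4.16. All 5 calls were lost without CuO 2 (3.07 to 3.60, adjusted p = 0.056 to 0.11), and all but that of pimr166 also without other arrays of the pair of groups. Without CuO 1 cfap299, pimr166 and ccdc83 stood at 4.60 to 5.17, and without CuO 3 npb and actn2b at 4.47 and 4.06, all called. Without control 1 npb was 4.39, without control 2 cfap299 was 4.76 and without control 3 actn2b was 4.35, called too. The transporter slco1f2 was at least 18.1-fold higher. Of 35 heat shock genes 10 rose and 1 fell, with the same counts adjusted over the list alone, but the list did not pass (adjusted p = 0.217). Its risen members included serpinh1b, the collagen chaperone (2.08, SE 0.47). Among 37 endoplasmic reticulum stress genes 6 fell and 1 rose, or 4 and 0 adjusted over the list alone (list adjusted p = 0.0537). The fallen included manf (-0.50 ± 0.46 and 2.16 ± 0.12, difference -2.66, SE 0.36) and creld2 (-2.19, SE 0.38), both known to be induced when unfolded protein accumulates.

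Of 51 collagen and matrix genes 18 rose under CuO and 0 fell, or 23 and 1 adjusted over the list alone, such as col5a3a (1.91, SE 0.42). Their median was 0.71 (adjusted p = 5.32e-05, or adjusted p = 0.583 with an estimated correlation). Of 41 epithelial and mucous genes 7 rose and 0 fell, or 6 and 0 adjusted over the list alone (adjusted p = 0.00113, or adjusted p = 0.588 with an estimated correlation). Of 52 ion transport genes 8 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.00514, or adjusted p = 0.612 with an estimated correlation). By array, their median was 0.31 on CuO 1 and -0.31 on CuO 2. On CuO 3, the CuO array low in eye transcripts, it was -1.71, within the control range (-2.06 to -1.49). The calcium-regulating hormone stc1 was 4.86-fold higher (SE 0.36) and the carbonic anhydrase ca4a 3.58-fold higher (SE 0.32). Of 21 lymphocyte markers 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (adjusted p = 0.00216, or adjusted p = 0.587 with an estimated correlation). Among them was the T cell co-receptor cd8a (-2.60 ± 0.54 and -5.20 ± 0.19, SE 0.38 of the difference).

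Of 36 immediate early genes 4 rose under CuO and 1 fell, or 2 and 1 adjusted over the list alone. Among them were the transcription factors egr1, at least 3.59-fold higher and not well above background on any control array, and egr2b (2.17, SE 0.38). The list passed at an adjusted p of 0.0483 (adjusted p = 0.780 with an estimated correlation), but not without control 1, control 3, CuO 1, CuO 2, ZnO 1 or NiO 3 (0.0510 to 0.188). Of 18 metallothionein and zinc transport genes 4 rose and 0 fell, with the same counts adjusted over the list alone. The metal-responsive transcription factor mtf1 rose by 1.26 (SE 0.29). The zinc exporter slc30a1a rose by 1.66 (SE 0.46, adjusted p = 0.0249), a call lost without control 1 (1.37), control 3 (1.64), CuO 1 (1.59) or CuO 2 (1.46). The metallothionein mt2 was 5.07 ± 0.23 and 4.55 ± 0.22 and missed the threshold (0.52, 95% interval -0.12 to 1.16, adjusted p = 0.197). The count of changed genes was 1830 without CuO 1, 1868 without control 3 and 6449 with array weights. With the mean of the oocyte markers as a covariate limma called 0 genes (627 at an unadjusted p under 0.05). Array position on the slide went with the group in every comparison, and each slide held 1 array per group, so a single slide gives no test. With the slide as a block, 2957 genes changed for CuO, 2919 for ZnO and 2540 for NiO.

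ZnO was compared with the controls to find the response to zinc oxide particles. Members of the oocyte, yolk and cell cycle lists fell here too. The claudin cldnd was -6.58 ± 0.94 under ZnO and 5.25 ± 0.38 in the controls (difference -11.83, SE 1.92, adjusted p = 0.0035). Its level went with the oocyte transcripts: under NiO it differed by -7.15, or -10.14 without NiO 1, the NiO array high in them. Members of the interferon list rose, such as the antiviral GTPase mxb (-0.12 ± 1.57 and -3.26 ± 0.55, 8.82-fold, adjusted p = 0.0087, log2 3.94 without ZnO 1 and 2.38 without ZnO 3). The glutathione transferase gstp1.1 was 3.32 ± 0.92 and 0.17 ± 0.53 (8.87-fold, adjusted p = 0.00457), and the quinone reductase nqo1 was 2.99 ± 0.54 and 0.51 ± 0.29 (5.60-fold, adjusted p = 0.00237). In all, 1725 genes rose and 1499 fell (4937 at an unadjusted p under 0.05). The balance turned with the scaling, to 684 and 1592 with ribosomal centring and 1200 and 1644 with a percentile over detected probes. At least 8-fold changes were called for 557 genes downward and 26 upward.

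The other largest falls under ZnO included the egg coat genes zp3f.1 (-11.73, SE 1.86), zp3a.1 (-10.19), zp2.3 (-10.12, or -10.87 without ZnO 2) and zpax4 (-9.51). They also held gtf3ab (-11.48, or -10.51 without ZnO 1), the histone hist1h2a6 (-10.03, or -9.25 without ZnO 1 and -10.67 without ZnO 2), tmsb5 (-9.88), the maternal mRNA-binding factor zar1 (-9.81, SE 1.52) and the survivin birc5b (-9.78, SE 1.60). The gene btg4 was at least 1782-fold lower and zp2l1 at least 1207-fold lower. Of the 52 oocyte genes 45 fell and 1 rose, or 46 and 1 adjusted over the list alone. Of 102 cell cycle genes 54 fell and 4 rose, or 65 and 4 adjusted over the list alone. The list median was -2.01 (adjusted p = 1.68e-15, or adjusted p = 0.587 with an estimated correlation). Its fallen members included ccnb2 (-1.32 ± 0.28 and 3.42 ± 0.15) and ccne1, the cyclin of S phase entry (-4.81, SE 0.65). Of 42 liver and plasma genes 5 fell and 1 rose, or 5 and 0 adjusted over the list alone. Vitellogenins made up 4 of the 5, with vtg4 at -6.82 (-7.67 without ZnO 3 to -5.76 without ZnO 2) and vtg7 at -6.37 (-7.38 without ZnO 3 to -4.87 without ZnO 2). The list median was -2.31 (adjusted p = 5.63e-05, or adjusted p = 0.780 with an estimated correlation). Without ZnO 1, the array low in liver and pancreas transcripts, its adjusted p was 0.281.

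The 10 largest rises under ZnO held illr1 (-0.61 ± 0.72, 83.2-fold, log2 7.68 without control 1 and 5.18 without control 2) and spry4, a feedback inhibitor of growth factor signalling (0.82 ± 0.36 and -3.40 ± 0.67, 18.6-fold). They also held the G protein gene gna15.4 (10.6-fold), antxr2b (9.70-fold), the stress kinase map3k20b (9.60-fold, log2 2.6 without control 2) and dhrs13l1 (9.28-fold). The glycosyltransferase b3gnt3.2 (3.66), the prostaglandin synthase ptgs2b (3.54) and the sodium pump subunit atp1a1a.5 (3.18) were called as well. Each of these calls was lost without control 1 (3.11, 3.15 and 2.34) or ZnO 2 (3.73, 3.48 and 2.82). That of b3gnt3.2 was also lost without ZnO 3 (3.13), that of ptgs2b without control 3 (2.92) or ZnO 3 (3.06), and that of atp1a1a.5 without control 2 (3.11) or ZnO 1 (3.12). Calls stayed at 4.55 for ptgs2b without control 2 and 4.07 for atp1a1a.5 without control 3. Of 35 interferon and antigen presentation genes 13 rose and 0 fell, with the same counts adjusted over the list alone. Their median was 0.74 (adjusted p = 0.00179, or adjusted p = 0.588 with an estimated correlation). The antiviral kinase pkz was 6.24-fold higher (SE 0.55, log2 3.30 without control 2), and the ubiquitin-like isg15 5.05-fold (adjusted p = 0.0291). The isg15 call was lost without control 1, control 2 or any ZnO array (1.99 to 2.36).

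Of 30 acute inflammation genes 9 rose under ZnO and 1 fell, or 9 and 2 adjusted over the list alone (list adjusted p = 0.0539). The acute-phase protein saa was called (2.79, adjusted p = 0.0157), but not without control 1 (2.62) or control 3 (2.29), and stood at 3.45 without control 2. Of 36 immediate early genes 13 rose and 1 fell, or 15 and 2 adjusted over the list alone (adjusted p = 0.00514, or adjusted p = 0.780 with an estimated correlation). Among them were the transcription factors egr3 (8.03-fold, SE 0.62, log2 3.63 without control 2) and atf3 (6.58-fold, SE 0.49). The latter also belongs to the endoplasmic reticulum stress list, of whose 37 genes 5 rose and 2 fell, or 4 and 0 adjusted over the list alone (adjusted p = 0.558). Of 44 antioxidant and glutathione genes 9 rose and 2 fell, with the same counts adjusted over the list alone (list adjusted p = 0.132). Of 44 proteasome genes 9 rose and 1 fell, or 12 and 1 adjusted over the list alone (adjusted p = 0.00608, or adjusted p = 0.780 with an estimated correlation). Examples were the proteasome activator psme4b (2.95-fold, SE 0.34) and psmd2 of the regulatory particle (3.12-fold, SE 0.29). As the mean of its probes psmd2 was 1.41 and not called (adjusted p = 0.11).

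Of 35 heat shock genes 10 rose under ZnO and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0301, or adjusted p = 0.588 with an estimated correlation). The chaperone hsp90aa1.1 was 6.03-fold higher (SE 0.50, log2 3.26 without ZnO 3) and lost its call as the mean of its probes (2.42, adjusted p = 0.088). Calls of hspb15 (2.41) and hsp70l (1.04) were lost without ZnO 2 (1.78 and 0.96) or control 3 (2.45 and 0.92), and further without control 1 for hspb15 (1.98) and ZnO 3 for hsp70l (0.95). Of 41 epithelial genes 14 rose and 0 fell, or 25 and 0 adjusted over the list alone (adjusted p = 1.59e-05, or adjusted p = 0.583 with an estimated correlation). The keratin krt1-c5 was 4.16-fold higher (SE 0.33), and the periplakin gene ppl was 2.95 ± 0.26 and 1.03 ± 0.61. The latter lost its call as the mean of its probes (1.75, adjusted p = 0.078). Of 51 matrix genes 17 rose and 0 fell, or 20 and 0 adjusted over the list alone (adjusted p = 5.95e-05, or adjusted p = 0.583 with an estimated correlation). They included the collagen cross-linker loxa (5.95-fold, SE 0.48) and the thrombospondin thbs4b (5.13-fold, SE 0.45).

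Of 18 metallothionein and zinc transport genes 3 rose under ZnO and 2 fell, with the same counts adjusted over the list alone. The zinc transporter slc39a3 rose 3.37-fold (SE 0.37). The exporter slc30a1b fell from -1.86 ± 0.75 to -6.99 ± 1.75 (-5.13, or -4.31 without ZnO 2 and -6.05 without ZnO 3) and was well above background on 1 of 3 ZnO arrays. The metallothionein mt2 was 3.65 ± 0.47 (-0.90, SE 0.29, adjusted p = 0.0425), a call lost when any of 10 arrays was left out (-1.06 to -0.63 over all 12 omissions). The oxygen sensor egln3 was called at 2.43 (adjusted p = 0.0483), its arrays overlapping the controls. That call was lost with quantile normalization and without any of 9 arrays, down to 1.71 without ZnO 3, and stayed at 3.13 without ZnO 1. The count of changed genes was 1535 without control 3, 1860 without ZnO 2, 2046 without control 1 and 1754 in a fit of the compared groups alone. With the oocyte covariate limma called 0 genes (326 at an unadjusted p under 0.05). Without ZnO 1 the heat shock, proteasome, lymphocyte, skeletal muscle, cartilage and oxidative phosphorylation lists lost their calls (adjusted p = 0.0531 to 0.185).

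NiO was compared with the controls to find the response to nickel oxide particles. Members of the heat shock list were among the genes that rose: hsp70l was 2.28 ± 0.16 under NiO and -0.07 ± 0.20 in the controls (5.11-fold, adjusted p = 0.00322), and hsp70.3 was 2.59 ± 0.24 and 0.32 ± 0.29 (4.84-fold, adjusted p = 0.00276). The myosin chaperone unc45b was 2.63 ± 0.72 and -1.19 ± 0.83 (14.1-fold, adjusted p = 0.00702). The basal epithelial regulator tp63 was 1.65 ± 0.34 and -0.27 ± 0.45 (3.78-fold, adjusted p = 0.00756), and the circadian repressor nr1d1 was 7.42-fold higher (adjusted p = 0.00935). Members of the cell cycle list and yolk genes fell, such as rad54l of homologous recombination (-4.04, SE 0.64) and vtg6 (-5.96, or -6.71 without control 2 and -5.29 without control 3). In all, 1272 genes rose and 1519 fell (4598 at an unadjusted p under 0.05), or 760 and 1517 with ribosomal centring. At least 8-fold changes were called for 395 genes downward and 46 upward.

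Egg coat genes were again among the largest falls under NiO, but with a wide spread, since NiO 1 lay near the controls. The gene btg4 was -4.68 ± 5.27 and 3.78 ± 0.32 (-8.45, SE 1.95, adjusted p = 0.015). The differences of zp3f.1, gtf3ab, zp2.3, zp3e, cldnd, retsatl, zp3a.1, zp2.1 and zpcx ran from -7.41 to -6.74 (adjusted p = 0.0175 to 0.0341). All 10 calls were lost without control 3 (-8.39 to -6.67, adjusted p = 0.056 to 0.096) and without NiO 2 (-7.60 to -5.52, adjusted p = 0.051 to 0.11). All but that of btg4 were lost without NiO 3 (-5.69 to -4.59), and several without control 1 or 2. Without NiO 1 all 10 stayed and moved to -11.41 to -9.50 (adjusted p of btg4 = 1.57e-05). Of the 52 oocyte genes 41 fell and 1 rose, or 43 and 1 adjusted over the list alone. Of 102 cell cycle genes 64 fell and 0 rose, or 73 and 2 adjusted over the list alone. The list median was -2.35 (adjusted p = 1.22e-20, or adjusted p = 0.583 with an estimated correlation). Its fallen members included cdc20, an activator of the anaphase-promoting complex (-3.96, or -4.84 without NiO 1 and -3.18 without NiO 2). Of 42 liver and plasma genes 4 fell, all vitellogenins, and 1 rose, or 4 and 0 adjusted over the list alone (list adjusted p = 0.0554). The gene vtg4 was at -6.21 (-7.01 without control 2 and -5.52 without control 3). The odorant receptor or42c5 was at least 14.4-fold lower.

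Of the 10 largest rises under NiO, 4 kept their calls with each array left out: unc45b, the natriuretic peptide gene nppal (4.97, or 3.48 without NiO 2, 4.24 without control 2 and 5.99 without NiO 1), the signalling ligand wnt4b (4.21, or 3.50 without NiO 2 and 4.83 without NiO 1) and pdyn (3.67, or 4.42 without control 2). The leptin gene lepb (5.25), the fin actinodin and2 (4.71), illr1 (3.95), npb (3.93) and cfap299 (3.79) lost their calls without control 3 (5.02, 2.87, 3.85, 2.90 and 3.63). The calls of and2 (5.05), illr1 (3.77), npb (3.90) and cfap299 (3.25) were also lost without NiO 3, as was that of atp1a1a.5 (4.09, or 3.27 without it). Calls were lost as well for lepb without control 1 (4.72) and illr1 without NiO 2 (3.63). That of cfap299 was further lost without control 1 (3.35), NiO 2 (3.53) or ZnO 2 (3.79). That of and2 was further lost without control 2 (4.78), NiO 1 (5.07), NiO 2 (4.01), CuO 1, CuO 2 or ZnO 3 (each 4.71). Some omissions kept the call but moved the value: lepb was 3.45 without NiO 2, 5.96 without NiO 3, 6.01 without control 2 and 6.34 without NiO 1. The value of illr1 was 2.75 without control 2 and 5.25 without control 1. Without control 1 and2 was 6.48, npb 4.74 and atp1a1a.5 3.26. The latter was 4.99 without control 3 and 4.83 without NiO 1, and cfap299 was 4.39 without control 2 and 4.59 without NiO 1. With all arrays the muscle cadherin cdh15 was at least 7.05-fold higher (a bound of log2 2.82), as it was not well above background on any control array. Its log2 difference from that dim control signal was 2.34 without NiO 2, under this bound, and 3.95 without NiO 3. Of 35 heat shock genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 0.0227, or adjusted p = 0.587 with an estimated correlation). The chaperone hsp90aa1.2 was 5.80-fold higher (SE 0.38). Of 61 skeletal muscle markers 5 rose and 0 fell, or 3 and 0 adjusted over the list alone (adjusted p = 0.000461, or adjusted p = 0.780 with an estimated correlation). The slow myosin smyhc1 was 10.6-fold higher (adjusted p = 0.0184), a call lost without control 3 (2.89), NiO 1 (2.98) or NiO 3 (3.33).

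Of 41 epithelial genes 13 rose under NiO and 0 fell, or 22 and 0 adjusted over the list alone (adjusted p = 3e-06, or adjusted p = 0.583 with an estimated correlation), with krt1-c5 3.80-fold higher (SE 0.33). Of 51 matrix genes 17 rose and 1 fell, or 18 and 1 adjusted over the list alone (adjusted p = 4.63e-05, or adjusted p = 0.583 with an estimated correlation). By array, the matrix median on NiO 1, the NiO array high in oocyte transcripts, was -1.18 and lay within the control range (-1.74 to -1.18). It was 0.08 on NiO 2 and -0.36 on NiO 3. The matrix protein gene ccn2a was 5.83-fold higher (SE 0.51) and loxa 4.58-fold (SE 0.48, lost without control 3 at 1.83). Of 37 clock genes 10 rose and 0 fell, or 11 and 2 adjusted over the list alone (adjusted p = 0.0237, or adjusted p = 0.587 with an estimated correlation). That list did not pass without control 2 (adjusted p = 0.0519) or NiO 2 (adjusted p = 0.0893). Its member hlfb, a clock output factor, was 8.89-fold higher, a call lost without control 2 (2.62), control 3 (2.98), NiO 2 (2.5) or NiO 3 (3.06) and kept without control 1 (3.86) or NiO 1 (3.89). Of 36 immediate early genes 11 rose and 0 fell, or 12 and 0 adjusted over the list alone (adjusted p = 0.000461, or adjusted p = 0.612 with an estimated correlation). Among them egr1, at least 3.04-fold higher, lost its call without control 3 (adjusted p = 0.0731) or NiO 2 (adjusted p = 0.0564).

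Of 52 ion transport genes 9 rose under NiO and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.00216, or adjusted p = 0.588 with an estimated correlation). The potassium channel kcnj1b fell (-2.19, SE 0.42). Of 18 metallothionein and zinc transport genes 2 rose and 1 fell, or 2 and 0 adjusted over the list alone. The transporter slc39a3 was 3.85-fold higher (SE 0.37), and mt2, at 3.95 ± 0.08, missed the threshold (-0.60, 95% interval -1.23 to 0.04, adjusted p = 0.16). In the endoplasmic reticulum stress list 3 of 37 genes rose and 3 fell, or 1 and 2 adjusted over the list alone (adjusted p = 0.973). The count of changed genes was 955 without control 3, 1459 without NiO 3, 1714 without NiO 2, 1722 without control 1 and 1491 in a fit of the compared groups alone. It was 4422 with array weights and 5 without the 4 arrays low in eye transcripts. With the oocyte covariate limma called 0 genes (791 at an unadjusted p under 0.05).

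**Figure D2:**
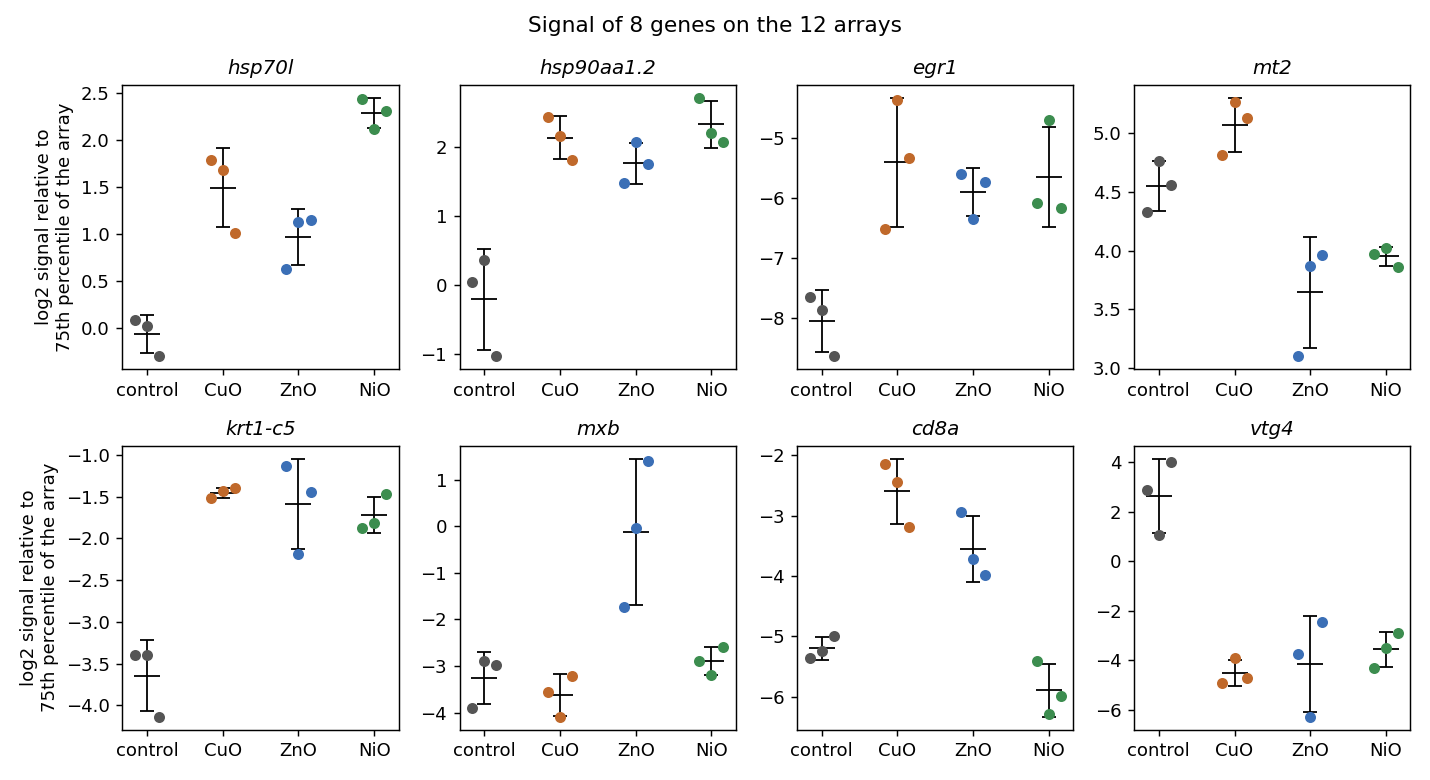
Log2 signal relative to the 75th percentile of the array (vertical axis) of 8 genes on the 12 arrays by group (horizontal axis), with points for pools and bars for mean and SD (n = 3). The points of hsp70l, hsp90aa1.2 and krt1-c5 lie above the controls in all 3 exposures and those of vtg4 below. Those of mt2 lie below the controls under ZnO and NiO, with a call under ZnO only.

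The fixed stress and metal genes gave few further calls. The gene hsp70l rose by 1.56 under CuO, 1.04 under ZnO and 2.35 under NiO. Relative to the median gene its rises were 1.14, 0.72 and 2.09, while the values of the other genes below are plain differences. The heme oxygenase gene hmox1a did not pass at 1.56, 1.24 and 1.01 in the same order (adjusted p = 0.161, 0.268 and 0.381). Neither did the cytochrome P450 gene cyp1a at 1.02, 1.14 and 0.53 (adjusted p = 0.113, 0.0846 and 0.415) or the glutathione peroxidase gene gpx1a at 0.82, 0.38 and 0.53 (adjusted p = 0.0664, 0.361 and 0.216). Differences of gclc, sod1 and cat lay between -0.77 and 0.75 and none was called. The copper transporter atp7a was at -0.63, 0.23 and 1.04, slc30a1a at 1.29 under ZnO (adjusted p = 0.0617, or called at 1.60 without control 2 and 1.74 without ZnO 1) and 0.98 under NiO, and egln3 at 0.85 under CuO and 1.13 under NiO, none of them called.

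Markers of immune and structural cells were called in part. Of 32 myeloid markers 1 rose under CuO, 7 under ZnO and 4 under NiO, and 1 fell in each, or 1, 10 and 3 risen and 1 fallen in each adjusted over the list alone. Their list tests passed (adjusted p = 0.023, 0.00514 and 0.023), with an adjusted p = 0.780 in each with an estimated correlation. They did not pass without control 1 (adjusted p = 0.230, 0.0685 and 0.251), nor for CuO without CuO 3 (adjusted p = 0.0707) and NiO without NiO 2 (adjusted p = 0.108). Of the 21 lymphocyte markers, 6 rose under ZnO and 1 under NiO, or 6 and 0 adjusted over the list alone. The ZnO test passed (adjusted p = 0.0408, or adjusted p = 0.780 with an estimated correlation), but not without control 3 (adjusted p = 0.0606) or ZnO 1 (adjusted p = 0.185). Of 32 cartilage and bone markers 8 rose under CuO, 8 under ZnO and 7 under NiO, and 1 fell in each, with the same counts adjusted over the list alone. Their tests passed (adjusted p = 0.00336, 0.0436 and 0.0227, or adjusted p = 0.583, 0.588 and 0.587 with an estimated correlation), but not for ZnO and NiO without control 2 (adjusted p = 0.101 and 0.0538), for ZnO without control 3, ZnO 1 or ZnO 2 (adjusted p = 0.0680, 0.0817 and 0.0514) or for NiO without NiO 1 (adjusted p = 0.0508). Of the skeletal muscle markers 8 rose under CuO and 6 under ZnO, or 0 and 0 adjusted over the list alone (adjusted p = 0.00424 and 0.0397, or adjusted p = 0.780 and 0.848 with an estimated correlation). The ZnO test did not pass without control 2, ZnO 1 or ZnO 2 (adjusted p = 0.148, 0.0531 and 0.303). Of 29 erythrocyte markers 3 rose under CuO, 1 under ZnO and 0 under NiO, and 1 fell in each, or 1, 0 and 0 risen and 1, 1 and 0 fallen adjusted over the list alone. Of 14 cardiac markers 1 rose under CuO only by this count, with 0 adjusted over the list alone. Of 20 complement genes 1 rose under CuO and 1 under NiO, with 0 adjusted over the list alone.

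Stress and metabolic lists not yet described moved in few members. Antioxidant genes numbered 6 risen and 3 fallen under CuO and under NiO, or 6 and 3 and 5 and 3 adjusted over the list alone. Proteasome genes numbered 2 risen and 1 fallen under CuO and 3 and 2 under NiO, or 1 and 1 and 2 and 1 adjusted over the list alone. Acute inflammation genes numbered 2 risen under CuO and 4 under NiO, or 0 and 1 adjusted over the list alone. Interferon genes numbered 4 and 3, or 4 and 0 adjusted over the list alone. Clock genes numbered 7 risen under CuO, and 8 risen and 1 fallen under ZnO, or 7, and 9 and 1, adjusted over the list alone. Ion transport genes numbered 10 risen and 2 fallen under ZnO, the same adjusted over the list alone (adjusted p = 0.0199, or adjusted p = 0.763 with an estimated correlation, and adjusted p = 0.0532 without ZnO 2). Of 15 copper handling genes 1 rose and 1 fell in every exposure, and adjusted over the list alone 1 rose under CuO. Of 23 iron handling genes 1, 2 and 1 rose and 1 fell in each, or 1 risen in each and 1 fallen under CuO adjusted over the list alone.

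Genes of the p53 pathway, 51 in number, showed 6 risen and 4 fallen under CuO, 9 and 0 under ZnO and 7 and 2 under NiO, the same adjusted over the list alone. Hypoxia and glycolysis genes, 53 in number, showed 6 and 2, 10 and 1, and 10 and 1, or 5 and 1, 5 and 0, and 8 and 1 adjusted over the list alone. Cholesterol synthesis genes, 28 in number, showed 4 and 4, 5 and 4, and 1 and 3, the same adjusted over the list alone. Aryl hydrocarbon receptor genes, 35 in number, showed 7 and 0, 8 and 1, and 4 and 0, or 5 and 0, 8 and 1, and 4 and 0 adjusted over the list alone. That list passed under CuO (adjusted p = 0.00618, or adjusted p = 0.588 with an estimated correlation). Of 80 oxidative phosphorylation genes 6, 7 and 6 rose and 0 fell, or 4, 4 and 3 adjusted over the list alone. The list passed under ZnO and NiO (adjusted p = 0.023 and 0.0277, or adjusted p = 0.86 with an estimated correlation), but not without control 1 (adjusted p = 0.189 and 0.241), for ZnO without ZnO 1 (adjusted p = 0.0905) or for NiO without NiO 2 (adjusted p = 0.551). Of 77 ribosomal protein genes 0 were called in any exposure. Their list tests went upward at an adjusted p = 0.0333 under CuO and 0.0485 under ZnO (adjusted p = 0.86 with an estimated correlation), against medians of -0.12 and -0.03 relative to the median gene, and were lost without control 1 (adjusted p = 0.627 and 0.735). The CuO test was also lost without CuO 2 or ZnO 1 (adjusted p = 0.120 and 0.0531), and the ZnO test without ZnO 2 (adjusted p = 0.370), any CuO array, NiO 2 or NiO 3 (adjusted p = 0.0522 to 0.0649).

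Of the marker lists added after the data were seen, 28 testis genes showed 5 risen and 4 fallen under CuO, 1 and 6 under ZnO and 3 and 1 under NiO. The 13 ovarian follicle genes showed 4 and 1, 5 and 1, and 3 and 0. The 24 pituitary and brain genes showed 4 and 0, 3 and 1, and 2 and 0. Of the eye genes 1 rose under CuO, and of the pancreas and intestine genes 3 fell under ZnO. Of 87 tests of the 29 fixed lists against control, 37 passed with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.583.

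**Figure D3:**
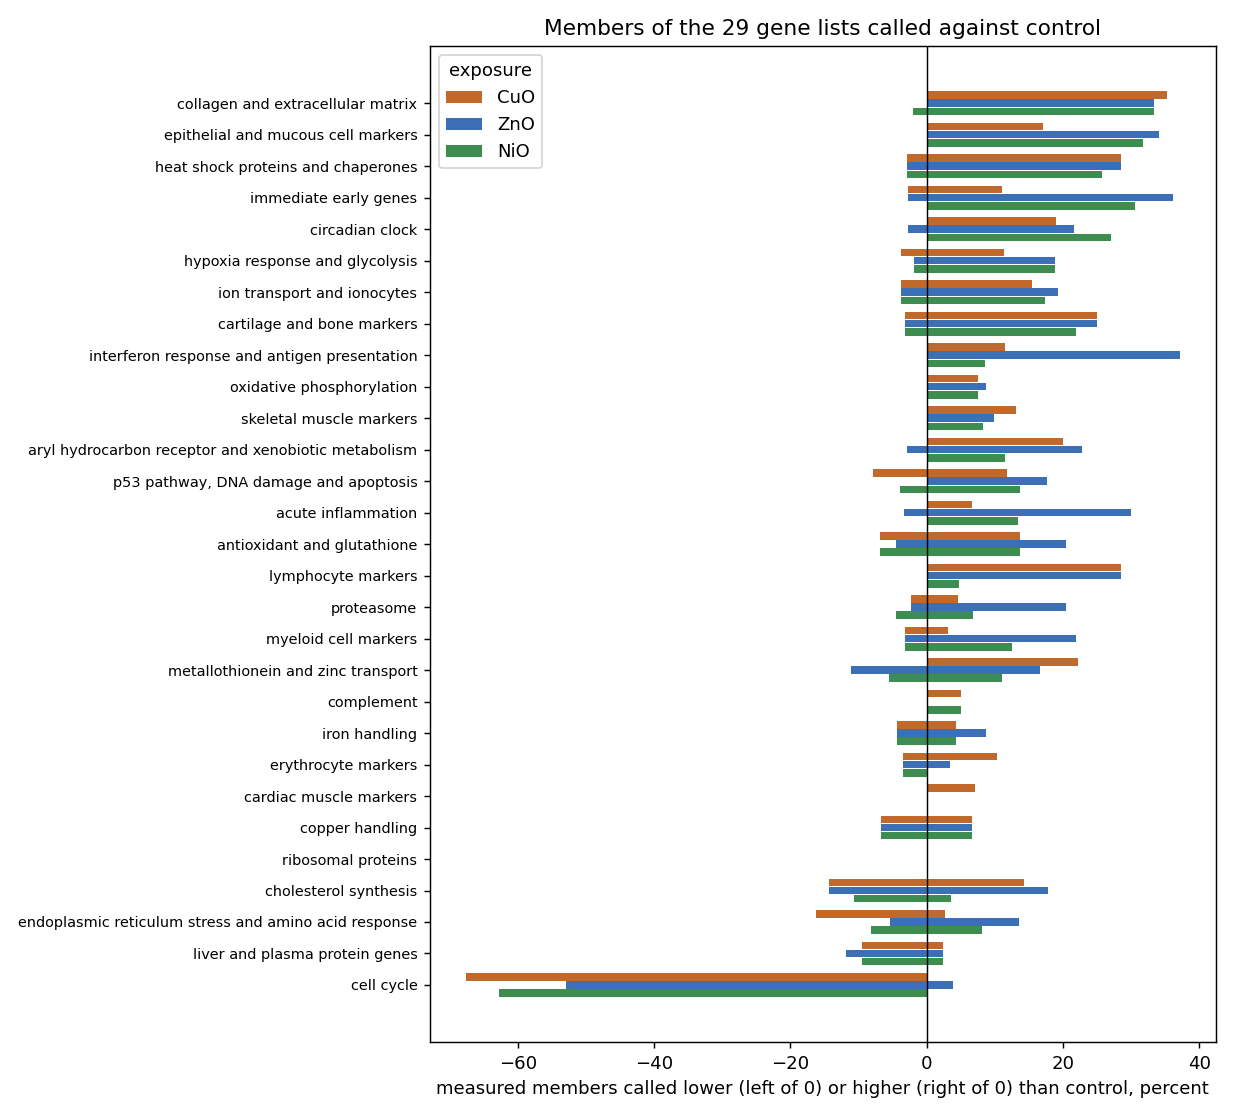
Percent of the measured members of each of the 29 lists (vertical axis) called lower (left bars) or higher (right bars) by limma at an adjusted p of 0.05, with 1 bar colour per exposure. Cell cycle genes have the largest share called lower in all 3 exposures.

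The exposures were set side by side to see which changes they share. Genes called higher in all 3 exposures numbered 711 and genes called lower 1184, against 19.9 and 24.7 for independent lists of the same sizes, and 1 gene was called in opposite directions. The 10 shared genes with the largest smallest difference were all lower. They were zp3f.1, gtf3ab, zp2.3, cldnd, zp3a.1, the cyclin ccna1 (-7.45 under CuO, -8.86 under ZnO and -6.69 under NiO), the histone mRNA-binding slbp2 (-8.12, -8.80 and -6.65), tmsb5 (-8.18, -9.88 and -6.65), the linker histone h1m (-8.22, -9.28 and -6.56) and the egg coat gene zpd (-7.97, -8.43 and -6.42). Under NiO, ccna1 ran from -8.80 without NiO 1 to -5.56 without NiO 3, and slbp2 from -8.75 without NiO 1 to -5.60 without NiO 2. The NiO calls of tmsb5, h1m and zpd were lost without control 3 (-6.49, -6.58 and -6.35), NiO 2 (-5.21, -5.53 and -5.56) or NiO 3 (-5.23, -4.68 and -4.97), and stayed at -9.51, -9.48 and -8.71 without NiO 1. Called in both CuO and ZnO were 942 genes upward and 1292 downward (197 and 205 for independent lists). In CuO and NiO these were 840 and 1358 (145 and 207), and in ZnO and NiO 994 and 1255 (175 and 181).

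Log2 differences of the exposures correlated across genes, which are not independent, at r = 0.851 for CuO and ZnO, 0.888 for CuO and NiO and 0.889 for ZnO and NiO. In 100 simulated draws of unchanged groups with shared controls r was 0.498. Covariances were 2.36, 2.1 and 2.16 against a simulated 0.329. Genes with the same sign made up 84.2%, 87.4% and 87.1% against 66.6%. Simulated groups gave 0 shared calls in 5 draws with limma. They were drawn with no difference between groups and no shift common to the controls, so a count near 0 followed from the setting. The 3 controls cannot be divided into parts of at least 2, so part of the excess may come from the shared controls. The mean of the 3 exposures differed from the controls in 4415 genes, 2399 higher and 2016 lower (5830 at an unadjusted p under 0.05), or 2497 without control 3. With ribosomal centring 1302 were higher and 2268 lower. The F test over the 4 groups called 2619 genes (4571 unadjusted), or 474 without control 3, 1151 without control 1 and 1675 without control 2. The shared calls numbered 660 without control 3, 1152 without control 1, 1114 without NiO 3 and 0 with the oocyte covariate. Exposed and control arrays did not overlap for 3437 genes higher and 2617 lower under CuO, 3207 and 2159 under ZnO and 2868 and 2472 under NiO, where chance gives 10% of the genes tested.

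Direct comparison of the exposures asked which genes tell the metals apart. Limma called 0 genes in each pair. At an unadjusted p under 0.05 there were 1249 for CuO against ZnO, 782 for CuO against NiO and 616 for ZnO against NiO. Nearest to the threshold was cd8a, at -2.60 ± 0.54 under CuO and -5.89 ± 0.44 under NiO (3.30, adjusted p = 0.0637). The B cell antigen cd37 (2.86), the sterol hydroxylase cyp8b1.2 (2.92) and the aminopeptidase lnpep (2.37) followed at an adjusted p of 0.0955. The transcription factor znf148, with the same adjusted p, was not well above background on any CuO array and at least 2.82-fold higher under NiO. Between CuO and ZnO, cyp8b1.2 was 0.57 ± 0.83 and -2.57 ± 0.17 (3.14, adjusted p = 0.137), and the neuronal pentraxin nptx2a differed by 2.43 (adjusted p = 0.155). The ammonia transporter rhcgl1 (-2.40), tmed1a (3.07) and the peptide transporter slc15a2 (3.73) had an adjusted p of 0.227. Between ZnO and NiO, the opioid growth factor receptors ogfr2 (2.62, adjusted p = 0.301) and ogfr1 (2.06, adjusted p = 0.32), cd37 (2.72), cd8a (2.34) and scamp5a (-2.65) came nearest. Without ZnO 3, 34 genes were called between CuO and ZnO, among them cyp8b1.2 (3.23), nptx2a (2.61) and slc15a2 (4.39), and znf148 was called between CuO and NiO. Without CuO 1, cyp8b1.2 was called in both comparisons (3.62 and 3.39), and cd8a was called between CuO and NiO without CuO 3 (3.6) or ZnO 1 (3.30). Array weights called 109 genes between CuO and ZnO and 71 between CuO and NiO. Arrays of the groups did not overlap for 790 genes higher and 1251 lower in CuO against ZnO, 918 and 733 in CuO against NiO and 683 and 376 in ZnO against NiO, of 12558 tested and with 10% given by chance.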

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

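The list tests between exposures were added to those against control after the data were seen. Probes with no current gene symbol, most of them designed on Ensembl transcripts or expressed sequence tags, took no part in the gene comparisons. Of 13562 such probes tested, 2037 were called higher than control and 1147 lower under CuO. Under ZnO these numbers were 1697 and 1155, and under NiO 1506 and 1002.

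Limma called 0 named genes between CuO and ZnO, CuO and NiO or ZnO and NiO (1249, 782 and 616 at an unadjusted p under 0.05), while 30 of 87 list tests between them passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.346). The values are median log2 differences of the members. Under CuO against ZnO, liver and plasma genes stood at 2.44, complement at 2.16, aryl hydrocarbon receptor genes at 0.72, lymphocyte markers at 0.30 and cartilage markers at 0.27. In the same comparison, endoplasmic reticulum stress genes stood at -0.64, cell cycle at -0.62, proteasome at -0.55 and interferon genes at -0.41. Under CuO against NiO, complement stood at 0.95, lymphocyte markers at 0.84, liver and plasma genes at 0.59, erythrocyte markers at 0.45, aryl hydrocarbon receptor genes at 0.40 and ribosomal proteins at 0.15. Endoplasmic reticulum stress genes stood at -0.45 there, immediate early genes at -0.37, proteasome and epithelial genes each at -0.30, cell cycle at -0.29, heat shock at -0.27 and p53 pathway genes at -0.24. Under ZnO against NiO, lymphocyte markers stood at 0.69, interferon genes at 0.59, cholesterol synthesis at 0.50, cell cycle at 0.33, antioxidant genes at 0.28 and proteasome at 0.25. Liver and plasma genes stood at -1.56 there and skeletal muscle markers at -0.30. By array, the liver and plasma median lay at -3.05 on ZnO 1 against 1.40 to 3.96 on the other 11 arrays, and the complement median at -2.75 on ZnO 1 against 0.57 to 2.83.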

How the results depend on the processing

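The settings added after the data were seen were normexp on the median signal, centring on ribosomal protein genes, the oocyte marker covariate and the 3 sets of arrays left out. Unless a value shows it, the cause was not tested for the results that changed. Counts of changed genes against control stayed within 1.5 times under the settings given first and with the block. For CuO, ZnO and NiO they were 3209, 3130 and 2869 with quantile normalization, 3072, 2844 and 2746 with a percentile over detected probes, and 3128, 3125 and 2729 without a background filter. They were 3015, 3091 and 2670 with signal above background on all 12 arrays, 2926, 2604 and 2489 with the mean of probes, and 3268, 3443 and 2930 with trend and robust variances. With a log2 difference of at least 1 they were 2958, 2972 and 2626, with normexp 3390, 3373 and 2997, and with ribosomal centring 2538, 2276 and 2277. Ribosomal centring split the calls into 607 higher and 1931 lower for CuO, 684 and 1592 for ZnO, 760 and 1517 for NiO and 1302 and 2268 for the mean of exposures, beside 1433 and 1714, 1725 and 1499, 1272 and 1519, and 2399 and 2016. The percentile over detected probes split ZnO into 1200 and 1644. The median of all genes shifted with the scaling, from 0.41, 0.32 and 0.27 to 0.32, 0.30 and 0.20 with quantile normalization, 0.34, 0.15 and 0.18 with the detected probes and 0.11, 0.01 and 0.07 with ribosomal centring. Between 75.5% and 88.4% of spots were well above background. In simulated CuO data with 200 of 12558 genes changed, the fit recovered 1 of 67 genes at a log2 difference of 1 and 51 of 66 at 4. Far fewer genes changed there than were called here, which makes the adjustment stricter, so recovery in the real comparisons may differ. The planned normexp on the mean signal was not run, because the files used here hold no such column.

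With the replicate number as a block, which is also the slide and the scan, 2957, 2919 and 2540 genes changed, 4148 for the mean of exposures, 2248 in the F test and 1704 shared. Same-numbered arrays correlated at r = -0.58 to 0.48 around their group means, 7 of 18 pairs over 0.1, and 4 of 12 arrays correlated best with their own number, so the numbers were not taken to pair the samples. All 37 list calls stayed with the block, while further lists passed: endoplasmic reticulum stress and acute inflammation in 1 comparison each, and liver and plasma, hypoxia and aryl hydrocarbon receptor genes in 2 each. Under it 187 values of named genes kept their direction and their side of the threshold, 3 no longer passed and 1 newly passed.

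The setting with the most reversals was the deposited table as labelled, by whose construction 10 of 12 columns hold another sample's array. Limma called 0 genes there for CuO, ZnO and NiO (254, 229 and 554 at an unadjusted p under 0.05), the mean of exposures (454) and the F test (195), with 0 shared. Lists that passed in 0 comparisons were heat shock, proteasome, ion transport, epithelial and clock genes. In 1 passed iron handling, antioxidant, endoplasmic reticulum stress, lymphocyte, skeletal muscle, cartilage, cell cycle, p53 and cholesterol genes, in 2 erythrocyte, cardiac, hypoxia and aryl hydrocarbon receptor genes, and in 3 complement and liver genes. The mean of a list minus that of all genes turned to -0.44 under CuO and -0.69 under ZnO for lymphocyte markers, -0.28 under CuO for skeletal muscle, -0.20, -0.35 and -0.0862 in the 3 exposures for cartilage, and -0.37 under CuO for matrix genes. It turned to 0.11 under CuO for cell cycle, to -0.0039 for proteasome, -0.14 for ion transport and 1.48 for liver genes under ZnO, and to -0.15 under NiO for clock genes. CuO differences of egg coat and oocyte genes turned positive: zp3e 2.78, zp3f.1 3.18, btg4 2.67, retsatl 3.34, zpcx 3.06, zp2.5 3.68, cldnd 3.93, gtf3ab 4.11, zp3a.1 3.30, ccnp 2.88, zp2l1 2.53, lectin 3.37, zp2.3 3.01, ccna1 2.32, slbp2 1.14, tmsb5 3.60, h1m 2.36 and zpd 2.69. So did aurka 1.12, ccnb1 1.75, manf 0.0692 and sdf2l1 0.0444. CuO differences turned negative for illr1 -2.86, cyp8b1.3 -0.90, tinagl1 -0.62, hsp90aa1.1 -0.20, mtf1 -0.48, ca4a -0.47, cd8a -0.86, il2rga -0.41, hmox1a -0.50, col5a3a -0.16, serpinh1b -0.21, krt1-c5 -0.19 and tp63 -0.18. Under ZnO they turned positive for cldnd 0.74, zp3f.1 0.86, gtf3ab 1.05, zp3a.1 0.57, zp2.3 0.13, hist1h2a6 1.5, tmsb5 0.29, zar1 0.066, birc5b 1.15, zpax4 0.48, ccne1 0.34, vtg4 0.0377, mt2 0.10, cat 0.0968 and zpd 0.56. ZnO differences turned negative for illr1 -1.24, gna15.4 -0.30, antxr2b -0.60, psmd2 -0.0157, psme4b -0.0546, krt1-c5 -0.66, thbs4b -0.11 and sod1 -0.0035. Under NiO they turned to -0.23 for and2, -0.13 for smyhc1, 0.27 for mt2, 0.26 for gclc, 0.0577 for sod1 and 1.33 for cat. CuO against NiO turned to -0.23 for cyp8b1.2 and -0.62 for cd37, and ZnO against NiO to -0.13 for ogfr2, -0.0439 for ogfr1, -0.86 for cd37, -0.61 for cd8a and 0.77 for scamp5a.

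With all probes, named or not, more features were tested by construction, and 7806 changed for CuO, 7309 for ZnO, 6378 for NiO, 11146 for the mean of exposures and 5689 in the F test, with 1 for CuO against ZnO, 10 for CuO against NiO and 11 for ZnO against NiO. Array weights gave 6449 for CuO, 4422 for NiO, 5484 in the F test, 109 for CuO against ZnO and 71 for CuO against NiO. The stricter adjusted p of 0.01 left 1363, 1150, 708, 2313 for the mean and 723 in the F test. Fits of only the groups compared, with fewer arrays by construction, gave 1754 for ZnO and 1491 for NiO. With an estimated correlation 0 of the 37 list calls stayed, so the heat shock, proteasome, ion transport, interferon, lymphocyte, myeloid, skeletal muscle, cartilage, liver, epithelial, matrix, cell cycle, oxidative phosphorylation, aryl hydrocarbon receptor, clock, immediate early and ribosomal lists each passed in 0. With the mean of probes all 37 stayed, antioxidant and endoplasmic reticulum stress genes passed in 1, aryl hydrocarbon receptor and clock genes in 2, and asns under ZnO turned to -0.55. Quantile normalization kept 31. Heat shock and acute inflammation passed in 1, oxidative phosphorylation and ribosomal proteins in 0, and sod1 turned to -0.0546 under CuO and -0.0516 under ZnO. Normexp kept 35, with endoplasmic reticulum stress and acute inflammation in 1, liver, aryl hydrocarbon receptor and clock genes in 2 and ribosomal proteins in 0, and gclc under NiO turned to 0.0023. Ribosomal centring kept 32, with endoplasmic reticulum stress and acute inflammation in 1, aryl hydrocarbon receptor genes in 2, and oxidative phosphorylation and ribosomal proteins in 0.

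The oocyte covariate nearly coincides with control against exposed, so it removes most of the contrast by construction. Limma then called 0 genes for CuO, ZnO and NiO (627, 326 and 791 at an unadjusted p under 0.05), for the mean (488) and in the F test (1057), 0 shared, 1 for CuO against NiO and 1 for ZnO against NiO. Heat shock, interferon, myeloid, skeletal muscle and ribosomal lists passed in 0, endoplasmic reticulum stress, complement, matrix and immediate early genes in 1, aryl hydrocarbon receptor genes in 2 and cholesterol synthesis in 3. List means, again minus that of all genes, turned to -0.17 under CuO and -0.42 under ZnO for skeletal muscle, -0.31 and -0.28 for ribosomal proteins, -0.0972 under ZnO for proteasome, and -0.35 under ZnO and -0.20 under NiO for oxidative phosphorylation. Without CuO 3, ZnO 1 and NiO 2 the counts were 4003, 3848 and 2556, with 4 for CuO against ZnO and 3 for CuO against NiO. Heat shock, proteasome, liver, oxidative phosphorylation, clock and ribosomal lists passed in 0, lymphocyte, myeloid, skeletal muscle, cardiac and hypoxia lists in 1 and aryl hydrocarbon receptor genes in 2. Without control 3 as well, ZnO had 1944, NiO 5, the F test 289, CuO against ZnO 1 and CuO against NiO 3, with 2 shared. Heat shock, proteasome, liver, oxidative phosphorylation and clock lists passed in 0, endoplasmic reticulum stress, lymphocyte, myeloid, hypoxia and ribosomal lists in 1 and cardiac and aryl hydrocarbon receptor lists in 3. Without these 4 and NiO 1 the counts were 1951, 1235 and 649, 2892 for the mean, 785 in the F test, 2 for CuO against ZnO, 8 for CuO against NiO and 552 shared. Proteasome, liver, oxidative phosphorylation and clock lists passed in 0, heat shock, lymphocyte, myeloid, cartilage, hypoxia and ribosomal lists in 1 and cardiac and aryl hydrocarbon receptor lists in 3. NiO keeps a single array in that fit, which is assumed to vary like the other groups.

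Leaving out 1 array in turn gave 1830 to 3421 genes for CuO (lowest without CuO 1, 1868 without control 3), 1535 to 3479 for ZnO (lowest without control 3, then 1860 without ZnO 2 and 2046 without control 1) and 955 to 2887 for NiO (lowest without control 3, then 1459 without NiO 3, 1714 without NiO 2 and 1722 without control 1). The mean of exposures ranged from 2497 to 4544, the F test from 474 to 2572 and the shared calls from 660 to 1795, each lowest without control 3. CuO against ZnO ranged from 0 to 34 (34 without ZnO 3), CuO against NiO from 0 to 2 (2 without CuO 3) and ZnO against NiO from 0 to 1. The count of 1 was reached in 2 of the 12 omissions, among them that of ZnO 3. Antioxidant, endoplasmic reticulum stress and proteasome lists passed in 0 to 1 comparisons, heat shock and lymphocyte lists in 1 to 2, and acute inflammation, liver, hypoxia and clock lists in 0 to 2. Cartilage and aryl hydrocarbon receptor lists passed in 1 to 3, and myeloid, oxidative phosphorylation and ribosomal lists in 0 to 3. Summed over the 12 fits, list calls stayed 402 times and were lost 42 times. Values of named genes kept their direction and their side of the threshold 2104 times, no longer passed 172 times, newly passed 10 times and reversed 6 times. Reversals were of atp7a under ZnO (-0.52 to 0.91), gclc under NiO (-0.27 to 0.35) and cat under NiO (-0.97 to 0.27).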

Other observations

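The tests of ovary RNA, of a lowering of oocyte transcripts by the exposures, of the order of the deposited columns and of all explanations for the eye transcripts were chosen only after the result was seen, as were the oocyte covariate and the marker lists of other tissues. Transcripts of pancreas, intestine and testis differed between exposures with the preset correlation and not with an estimated one. The median of 26 pancreas and intestine genes was 3.75 higher under CuO than under ZnO (limma camera adjusted p = 3.65e-21, or adjusted p = 0.202 with an estimated correlation). Under ZnO against NiO it stood at -2.96 (adjusted p = 1.77e-21, or adjusted p = 0.202 with an estimated correlation). By array it lay at -4.22, -0.53 and 2.4 under ZnO, 3.00 to 4.18 under CuO, 2.47 to 2.87 under NiO and 0.98 to 2.72 in the controls. The median of 28 testis and sperm genes was 1.61 higher under CuO than under ZnO (adjusted p = 4.26e-09) and stood at -1.58 under ZnO against NiO (adjusted p = 2.19e-12), each with an adjusted p = 0.202 with an estimated correlation. It lay at -4.57, -4.34 and -2.21 under ZnO, -3.60, -1.32 and -0.87 under CuO, -2.88, -2.02 and -1.17 under NiO and -2.92 to -2.51 in the controls, so the arrays of ZnO overlapped those of CuO and NiO.

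The first 3 principal components of 12294 genes held 38%, 26% and 11% of the variance. Among the 500 genes with the largest weights were 41 of 52 oocyte genes on the first, 30 of 32 eye genes on the second and 25 of 26 pancreas and intestine genes on the third. The oocyte list shares 1 gene with the ion transport list and 1 with the p53 list, and none with the cell cycle list.

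Oocyte transcripts were high in the controls and NiO 1, and the labels name gill only. Dilution by ovary RNA stays open for the 942 genes called higher in both CuO and ZnO. There NiO 1 lay at a median place of 0.158 between the exposed mean (0) and the control mean (1), below the bound set in advance against dilution. That bound did not allow for the lower oocyte median of NiO 1 (1.58 against 2.76 to 3.05 in the controls), so it could not decide. Over the same genes NiO 2 lay at 0.00387 and NiO 3 at 0.0364, and over the 1292 genes called lower NiO 1 lay at 0.343. Ovary RNA in these pools stays open for the oocyte genes. Of these, 40 of 52 lay higher on all 4 arrays than on every other array. The 4 arrays were named after these genes were seen high on them, so the count cannot tell causes apart. A lowering of oocyte transcripts by the exposures stays open too, with 8 exposed arrays over 3 below the lowest control, because the labels give neither sex nor dissection notes. Female fish in NiO 1 cannot be told apart from an exposure that lowers vitellogenin. The median of 5 vitellogenins there differed by -6.68 from the control mean. This median was low on all 9 exposed arrays (-4.78 to -1.72), so the bound set for this test could not tell sex. It hides vtg5, which lay at 0.225 to 2.27 on the exposed arrays and overlapped the controls (0.664 to 3.79).

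The deposited series table and the scanner files hold different arrays for 10 samples. All 12 columns of the table hold the arrays in order of slide and then of position, so filling in slide order is a candidate explanation. Scanner files attached to the wrong samples stay open: of 100 splits of the arrays, 1, the labelled one, gave as many genes in the F test (2619, highest other 2530), but each labelled group sits at 1 slide position and the count is the same whichever group is called control, so the bound set for this test could not decide. Array position on the slide goes with the group and cannot be told apart from it. Before any centring of the spike-ins, 1 of 10 spike-in probes shifted by 1.39 between position 1 and the others. The median for the called genes was 1.48, and the other 9 probes lay at -0.28 or lower. With the spike-ins centred on each array, that probe shifted by 1.67 and the other 9 moved between -0.73 and -0.01. Centring makes the 10 shifts balance, so the centred values of the 9 depend on the large one.

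Eye transcripts were low on 1 array of each group. An exposure is argued against, since all 4 groups including the controls hold such an array, and so is the slide, since all 3 slides do. Eyes or other head tissue in some pools and not in others stay open, with 31 of 32 eye genes lower on all 4 arrays than on every other array. The 4 arrays were named after these genes were seen low on them, so the count cannot tell causes apart. No biological explanation other than the exposure was tested.

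Other splits of the samples were counted for each test. With 6 arrays there are 10 splits, too few for a share under 0.05. CuO gave 3147 genes against a highest other of 1, ZnO 3224 against 0 and NiO 2791 against 0, each with 1 split as large. Between exposures all 10 splits gave as many as the real count of 0, which any split must, so this share carries no information. The highest other was 26 for CuO against ZnO, 0 for CuO against NiO and 1 for ZnO against NiO. A random split of the arrays was argued against for the mean of exposures (4415 genes, highest other 1008, 1 of 100 splits as large). The same held for the F test (2619, highest other 2530, 1 of 100). A share of 1 of 100 is the lowest that these splits can give. The split with 2530 kept the 3 controls together and mixed the exposures. The F count therefore speaks for controls against the rest, not for differences between the metals. Controls also share a slide position, so neither count tells the cause. A random split was not excluded for the number of list calls (37, highest other 45, 18 of 100 splits as large).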
